A study of Mus musculus with 6 samples.

How the data were processed

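RNA sequencing values from 6 libraries of mouse cultures labelled as synovial fibroblasts were used, 3 libraries labelled non-primed and 3 labelled primed. Groups and replicate numbers were taken from the sample labels. Libraries were made with a stranded mRNA kit, per the labels' protocols. Of the tools the authors used, the submitters' processing notes name cutadapt 1.18, STAR 2.6.1c, Subread 1.6.1 with featureCounts, DESeq2 1.24.0 and the GRCm38 genome build. How these were combined, the strand setting and the treatment of reads that match several places are not given in the sources used here, so near-identical genes, overlapping genes and antisense pairs are uncertain. The deposited values are regularized-log (rlog) values on a log2 scale, as the authors named the file. Of these tools DESeq2, which the authors' notes list, offers this transformation, which divides counts by size factors and draws genes of low count towards their mean. Whether it was run blind to the groups is not stated. The transformation shrinks differences of low genes, so a difference here is on the rlog scale and can understate the change of such genes. Counts were not used here, the depth of each library is unknown and no interval or floor that needs it is given. Of 55413 genes, 19433 were listed at 0 in all 6 libraries. All 55413 gene identifiers matched a symbol of the GENCODE annotation of GRCm38, from which coordinates were taken, counted from 1. Mitochondrially encoded transcripts were not analysed here. No 2 libraries of a group held identical values.

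Genes with a mean value of at least 4 over the 6 libraries were tested, which left 15129 genes, 13331 of them protein-coding. The 6 libraries entered 1 model in limma 3.58.1 (R 4.3.3) with the group as the only term. Variances were moderated with a trend over mean expression, tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01 between genes, with the correlation estimated from the data, on ranks, and with fry. In all, 51 lists were written, of which 45 had at least 5 tested members, and their p-values were adjusted over these 45. Of 1193 list entries, 1177 matched a gene in the table, 7 of them through an older symbol. The test, the filter, the lists, the rule for named genes and most of the alternatives were fixed before the data were examined. A list of pigment-cell genes, a list of targets of the pigment-cell regulator MITF, centring on ribosomal protein genes, the counts per list without non-primed replicate 3 and the test of MITF targets found in no other list were added after the data were seen.

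Named genes are the 12 with the largest rise and the 12 with the largest fall among genes past the threshold whose groups do not overlap, leaving out model names and pseudogenes, a fixed list of 22 genes of complement, inflammation, metabolism, senescence and matrix, of which 21 were tested, and up to 4 members with the smallest p in each list described. Other genes were chosen after their values were seen, as the members that moved against their list or for the cell type they mark. The alternatives were the replicate number as a block, no filter, a mean of at least 7, median centring, quantile normalization, a constant prior variance, library quality weights and leaving out each library in turn. The procedure was tested on simulated data for the same comparison over 15129 genes in 5 runs. It recovered 23.58% of genes changed by 1 on the log2 scale, 53.43% of those changed by 2 and 82.73% of those changed by 4, and 4.324% of calls were false. A planted list was called, and 0 of 20 random lists were. The simulated noise was drawn for each gene by itself, and far fewer genes were changed than were called in the data. These shares therefore need not hold for the real libraries, where genes vary together.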

Results

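RNA sequencing was used to compare cultures labelled as synovial fibroblasts, the stromal cells of the joint lining, grown from digested paws of wild-type BALB/c mice, an albino strain. The mice had received monosodium urate (MSU) crystals, the crystals that cause gout, in the paw. In 3 libraries labelled non-primed the paw had been injected 1 time, and in 3 libraries labelled primed it had been injected 2 times. Both groups were taken 9 days after the last injection. The values are regularized-log (rlog) expression values on a log2 scale for 55413 genes, of which 19433 were listed at 0 in all 6 libraries. Counts were not used here, so the depth of each library is unknown and no counting error is given. The median value over the 15129 genes tested lay between 10.4 and 10.6 in every library. The labels do not say that the libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical.

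The design asks how fibroblasts of a joint injected again with crystals differ from those of a joint injected 1 time. The 2 groups differed in 7476 of the 15129 genes tested. The pigment-cell genes Tyrp1, Dct and Pmel were among the 15 most abundant protein-coding transcripts of each library labelled non-primed and had means of 5.32, 5.28 and 7.34 in the libraries labelled primed. The melanosome glycoprotein gene Gpnmb ranked 1, 1 and 2 in non-primed replicates 1, 2 and 3 and kept a mean of 16.8 in the libraries labelled primed, and the pigment enzyme gene Tyrp1 ranked 2, 2 and 6. In the libraries labelled primed, the matrix metalloproteinase gene Mmp3 ranked 3, 1 and 1, the osteopontin gene Spp1 ranked 1, 4 and 3 and the ferritin gene Fth1 ranked 2, 2 and 4. The number of injections was not separated from the cell type in these libraries. Below, rose, fell, higher and lower describe differences between the groups, and none of them can be assigned to the repeated injection.

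Of the 15129 genes tested, 4113 were higher and 3363 were lower in the libraries labelled primed by limma at an adjusted p under 0.05. The called genes included 2316 that were higher and 842 that were lower by at least 2 on the log2 scale. The 3 values of one group all lay above the 3 of the other in 9449 genes, 62.46% of those tested, where chance gives 10%. Higher genes made up 55.02% of the calls with the values as deposited. After quantile normalization they made up 41.5%, with 3522 higher and 4965 lower, and after centring on ribosomal protein genes 45.35%, with 3239 higher and 3904 lower. Libraries correlated across genes at r = 0.9319 to 0.9873 within the non-primed group, 0.9796 to 0.9848 within the primed group and 0.6768 to 0.8131 between groups. The lowest correlations within the non-primed group were those of replicate 3, at 0.9319 and 0.9432.

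Genes of melanin synthesis and the melanosome, the pigment granule, were among those with the largest falls. Tyrp1 (ENSMUSG00000005994, chromosome 4, 80834123 to 80851719, GRCm38) had a mean of 18.57 ± 0.567 (SD, n = 3) in the libraries labelled non-primed and 5.32 ± 0.329 (SD, n = 3) in those labelled primed, a difference of −13.26 (SE 0.32, limma adjusted p = 2.7e-05). Dct (ENSMUSG00000022129, chromosome 14, 118012790 to 118052244), which encodes dopachrome tautomerase, differed by −12.98 (SE 0.22, limma adjusted p = 1.1e-05). The tyrosinase gene Tyr differed by −11.33 (SE 0.31), the melanosome matrix gene Pmel by −10.63 (SE 0.21), the melanosome transporter gene Slc45a2 by −11.62 (SE 0.78) and the melanocortin receptor gene Mc1r by −10.01 (SE 0.72). The other genes among the 12 with the largest falls were Ptgds at −11.21, Foxr2 at −10.38, Tspan10 at −10.11, Pianp at −10.08, Fkbp6 at −10.04 and Car14 at −9.67, and all 12 had a limma adjusted p of 0.00102 or less. In a list of 22 pigment-cell genes written after the most changed genes had been seen, 21 were lower and 1 was higher, the endothelin receptor gene Ednrb at 3.80. That list had a median of −7.36, and because it was written from these libraries its count is not independent evidence of its direction. Adjusted over the 2 lists added after the data were seen, camera gave p = 3.2e-12, and adjusted p = 0.12 with an estimated correlation.

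**Figure D1:**
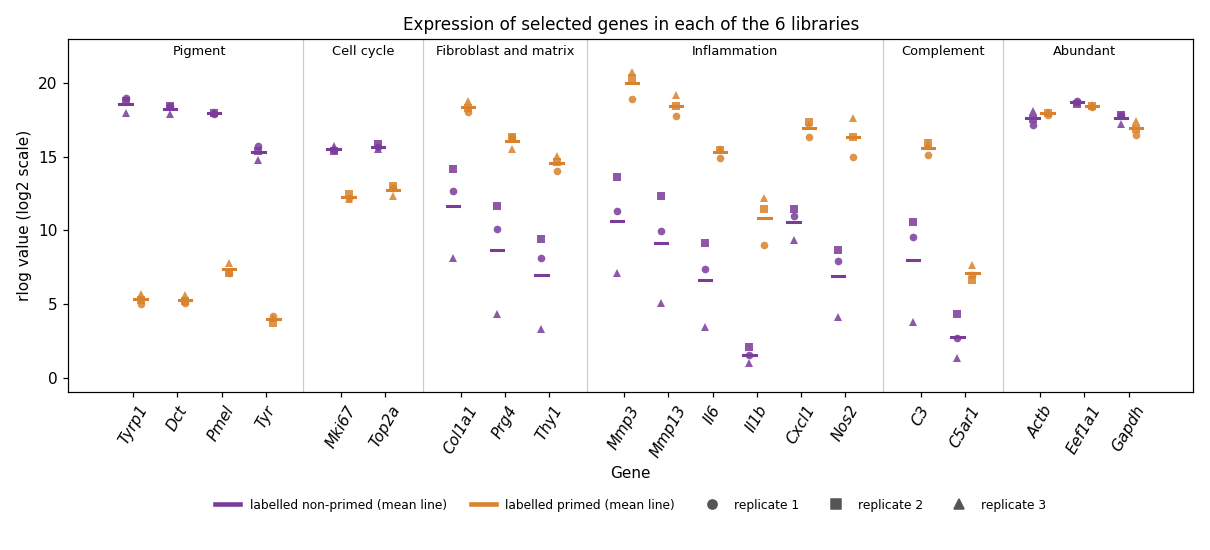
Expression of 20 genes (x axis, grouped by function) as rlog values on a log2 scale (y axis) in each library, with a symbol per replicate and a line at the group mean. Tyrp1 had a mean of 18.57 in the libraries labelled non-primed and 5.32 in those labelled primed, Mmp3 had means of 10.66 and 20.02, and non-primed replicate 3 lay lowest of its group for Col1a1, at 8.13.

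Genes of cell division fell together with the pigment genes. All 32 tested genes of the cell cycle and mitosis list were lower in the libraries labelled primed, 32 also when adjusted over the list alone, with a median of −2.55. The proliferation marker Mki67 differed by −3.28 (SE 0.15, limma adjusted p = 0.000132), the kinetochore motor gene Cenpe by −2.24, Cdca3 by −3.12 and the spindle checkpoint kinase gene Bub1 by −2.54. Of 32 DNA replication genes, 28 fell, 29 when adjusted over the list alone, with a median of −2.12. The DNA ligase gene Lig1 differed by −2.65, the helicase subunit gene Mcm2 by −3.04, the ribonucleotide reductase gene Rrm1 by −2.08 and the clamp loader gene Rfc4 by −2.21. Camera gave adjusted p = 1.2e-17 and 8.6e-12 for these lists, and adjusted p = 0.453 for both with an estimated correlation. The pigment-cell list had its median of −7.36 in the same contrast.

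Genes of inflammatory mediators were among those with the largest rises. The 12 genes with the largest rises were U90926 at 9.73, the chemokine genes Cxcl3 at 9.67 and Cxcl5 at 8.83, the inducible nitric oxide synthase gene Nos2 at 9.43, the collagenase gene Mmp13 at 9.37, the stromelysin gene Mmp3 at 9.36, the interleukin-1 genes Il1b at 9.34 and Il1a at 9.19, the thrombospondin gene Thbs4 at 9.24, the acute-phase gene Saa3 at 9.13, the interleukin-33 receptor gene Il1rl1 at 8.94 and the lectin receptor gene Clec4e at 8.83. Their standard errors lay between 0.85 and 1.75 and their limma adjusted p values were 0.00622 or less. Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139, GRCm38) had a mean of 1.53 ± 0.539 (SD, n = 3) in the libraries labelled non-primed and 10.9 ± 1.67 (SD, n = 3) in those labelled primed. Of 19 chemokine genes tested, 17 rose, 18 when adjusted over the list alone, with a median of 6.85, among them Cxcl1 at 6.35 (SE 0.57, limma adjusted p = 0.000546), Ccl4 at 6.28, Ccl3 at 8.14 and Cx3cl1 at 5.27. The monocyte chemokine gene Ccl2 rose by 8.14 (SE 1.79, limma adjusted p = 0.0105). In non-primed replicates 1, 2 and 3 Ccl2 lay at 10.84, 11.9 and 4.74 and Il6 at 7.38, 9.15 and 3.44. As written, the chemokine list held 24 genes, and the rest lay below the expression filter. Of 27 genes for cytokines and growth factors of inflamed synovium, 24 rose, 26 when adjusted over the list alone, with a median of 5.79. Il6 rose by 8.64 (SE 1.35, limma adjusted p = 0.00305), Il11 by 5.41, the osteoclast factor gene Tnfsf11 by 7.12, Csf1 by 4.22 and Csf3 by 7.28. Of 21 NF-kB targets and inhibitors, 19 rose, 19 also when adjusted over the list alone, with a median of 2.48, among them Nfkbiz at 3.21, Nfkbia at 2.82 and Bcl3 at 4.43. These 3 lists had camera adjusted p of 1.4e-05 or less, and adjusted p = 0.453 with an estimated correlation. In the same contrast the pigment-cell list had a median of −7.36, and 19 of 19 macrophage and monocyte markers rose with a median of 4.46.

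Of 20 inflammasome and interleukin-1 family genes, 13 rose and 4 fell, or 13 and 5 when adjusted over the list alone, with a median of 2.92. The inflammasome sensor gene Nlrp3 rose by 5.31 (SE 0.54, limma adjusted p = 0.00076), Aim2 by 3.75 and the receptor gene Il1r1 by 6.14, whereas the adaptor gene Pycard was lower at −2.57, Il18 at −1.44, Txnip at −1.52 and Casp8 at −0.92. Of 23 complement genes, 19 rose and 1 fell, the complement regulator gene Cd46 at −1.44, or 20 and 1 when adjusted over the list alone, with a median of 3.68. The central component gene C3 rose by 7.64 (SE 1.71, limma adjusted p = 0.0112), the factor B gene Cfb by 5.38 (SE 0.90, limma adjusted p = 0.00382), the receptor gene C5ar1 by 4.30 (SE 0.77, limma adjusted p = 0.00491), Masp1 by 2.10, Cr1l by 1.14 and Cfi by 4.10. C3 lay at 9.57, 10.57 and 3.74 in non-primed replicates 1, 2 and 3. Col1a1 lay at 12.65, 14.17 and 8.13 there, also lowest in replicate 3. The rise of C3 therefore cannot be told apart from a difference in cell content. C3ar1 rose by 4.02 (SE 1.06, limma adjusted p = 0.0209), a call that was lost without primed replicate 1, at limma adjusted p = 0.0609, and without primed replicate 3, at 0.0756. The receptor gene C5ar2 lay below the expression filter, with values of 0.589, 0.90 and 0.23 in the libraries labelled non-primed and 2.55, 1.55 and 2.34 in those labelled primed. As written, the inflammasome and complement lists held 25 and 28 genes, and all that were not tested lay below this filter. Of 35 interferon-stimulated genes, 11 rose and 24 did not pass, 11 also when adjusted over the list alone, with a median of 2.38 that was 1.21 without non-primed replicate 3, where 22 were higher and 2 lower. Stat2 rose by 2.23, Iigp1 by 6.16, Zbp1 by 7.51 and Oas3 by 5.56. Of 16 genes of MHC class I and II presentation, 15 rose, 15 also when adjusted over the list alone, with a median of 3.06, among them B2m at 2.63, H2-D1 at 2.18, H2-Ab1 at 7.17 and H2-DMa at 2.14. The class II genes H2-Aa, H2-Eb1 and Ciita of this list lay below the expression filter, with highest values of 1.13, 5.70 and 1.80. MHC genes and the pair C4a and C4b have near-identical copies, and their values are uncertain where reads were split between them. Camera adjusted p was 0.0117 for the inflammasome list, 0.00016 for complement, 0.00083 for interferon-stimulated genes and 0.00012 for MHC. With an estimated correlation the adjusted p values were 0.486, 0.453, 0.673 and 0.453. The inflammasome call was lost at a mean of at least 7, at camera adjusted p = 0.0599 and a median of 1.81, and the interferon call was lost under fry, at adjusted p = 0.158. The pigment-cell median was −7.36 and the macrophage and monocyte median 4.46 in the same libraries. Clec4e, C3ar1, Pianp and the hexokinase gene Hk2 lie on chromosome 6, whose 546 protein-coding genes with a mean of at least 7 had a median shift of −0.53 against such genes of all chromosomes.

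Matrix genes were higher in the libraries labelled primed. Of 21 collagen genes, 18 rose, 20 when adjusted over the list alone, with a median of 5.39. Col1a1 had a mean of 11.65 ± 3.14 (SD, n = 3) in the libraries labelled non-primed and 18.39 ± 0.391 (SD, n = 3) in those labelled primed, a difference of 6.74 (SE 1.45, limma adjusted p = 0.00986). Col8a1 rose by 5.31, Col5a1 by 3.38, Col5a3 by 4.39 and Col24a1 by 6.71. Of 37 other matrix genes, 34 rose, or 34 with 1 lower when adjusted over the list alone, with a median of 5.02, among them the fibronectin gene Fn1 at 4.31, the versican gene Vcan at 5.90, Ecm1 at 4.78 and Fbn2 at 4.98. Of 27 metalloproteinases and inhibitors, 22 rose, 22 also when adjusted over the list alone, with a median of 5.02, among them Timp2 at 2.50, the aggrecanase gene Adamts5 at 4.40, Adamts7 at 3.72 and Ctsl at 2.33. Of 23 contractile and myofibroblast genes, 21 rose, 22 when adjusted over the list alone, with a median of 3.06, among them the calponin genes Cnn1 at 6.64 and Cnn2 at 2.55, Palld at 2.81 and Cald1 at 1.90. Of 27 genes of the TGF-beta and BMP response, 24 rose and 2 fell, Id2 at −1.88 and Bambi at −1.34, with the same counts when adjusted over the list alone and a median of 3.96. Smad7 rose by 3.17, Tgfb1i1 by 5.12, Fstl1 by 3.96 and Smad6 by 3.58. Of 25 Wnt pathway genes, 17 rose and 2 fell, or 17 and 3 when adjusted over the list alone, with a median of 3.30. Rspo3 rose by 5.09, Wnt11 by 4.41, Wnt16 by 4.61 and Fzd1 by 2.40, and the target genes Axin2 at −1.80 and Lef1 at −2.33 were lower. All of these lists had a camera adjusted p of 0.0016 or less, and adjusted p = 0.453 with an estimated correlation. The pigment-cell median in the same contrast was −7.36. Collagen and other matrix genes, 58 in all, had a median deficit against the primed mean of 4.44, 3.92 and 7.26 in non-primed replicates 1, 2 and 3.

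Lists of fibroblast subset markers and positional genes were also higher in the libraries labelled primed. Of 18 markers of synovial lining fibroblasts, 13 rose, or 13 with 1 lower when adjusted over the list alone, with a median of 4.38, among them Sema3c at 4.57, Htra4 at 5.20, Hbegf at 3.81 and Pdpn at 5.12. The lubricin gene Prg4 rose by 7.36 (SE 1.78, limma adjusted p = 0.0152). Of 15 markers of sublining fibroblasts, 14 rose, 14 also when adjusted over the list alone, with a median of 5.34, among them Tnxb at 4.94, Dpt at 5.34, Ly6c1 at 5.33 and Cd34 at 5.32. The fibroblast surface gene Thy1 rose by 7.61 (SE 1.5, limma adjusted p = 0.00702). In non-primed replicates 1, 2 and 3 Prg4 lay at 10.10, 11.64 and 4.33 and Thy1 at 8.14, 9.43 and 3.32. Of 24 HOX and limb patterning genes, 18 rose and 3 fell, Shox2 at −1.60, Meis2 at −2.71 and Hoxd4 at −1.85, or 19 and 3 when adjusted over the list alone, with a median of 4.33 that was 1.94 at a mean of at least 7, where camera adjusted p was 0.0473. Hoxc11 rose by 5.59, Hoxa9 by 3.02, Hoxc10 by 6.01 and the hindlimb gene Pitx1 by 6.22. As written, the lining, sublining and positional lists held 20, 21 and 28 genes, and the rest lay below the expression filter. Because the filter takes the mean over 6 libraries, a marker under 4 in the non-primed group passes only if higher in the primed group. Camera adjusted p was 0.00108, 0.000114 and 0.000356 for the lining, sublining and positional lists, and 0.453, 0.453 and 0.486 with an estimated correlation. The pigment-cell median was −7.36 in the same libraries.

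**Figure D2:**
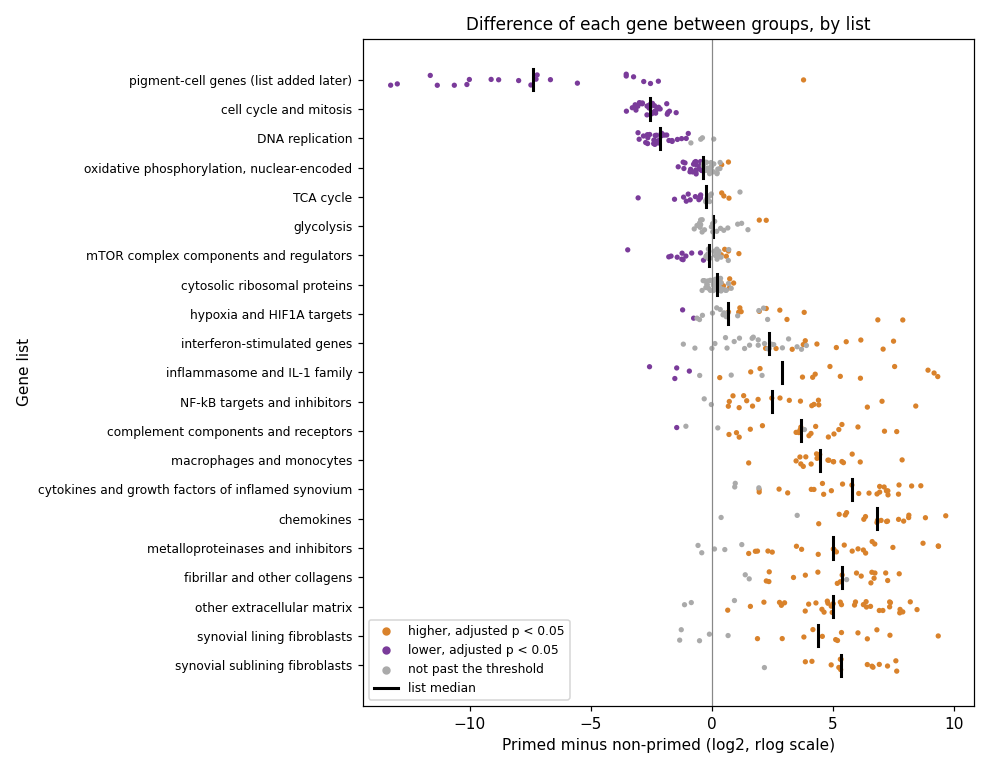
Difference of each tested gene between the libraries labelled primed and non-primed (x axis, log2 on the rlog scale) for 21 gene lists (y axis), with a point per gene coloured by its call and a black line at the list median. The median was −2.55 for cell cycle and mitosis genes, 6.85 for chemokines and 0.04 for glycolysis. The sign for glycolysis turned under median centring, quantile normalization, ribosomal protein centring and library quality weights. It also turned without non-primed replicate 3 and without primed replicate 3.

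Genes of oxidative phosphorylation and the TCA cycle were lower as lists in the libraries labelled primed. Of 49 nuclear-encoded genes of oxidative phosphorylation, 24 fell and 2 rose, with the same counts when adjusted over the list alone and a median of −0.35 that was −0.613 under ribosomal protein centring, among them Ndufa5 at −1.38, Ndufs1 at −1.15, Ndufa4 at −1.18 and Cox5b at −1.10. Of 23 genes of the TCA cycle, 11 fell and 3 rose, or 11 and 4 when adjusted over the list alone, with a median of −0.24 that was −0.45 under quantile normalization and −0.507 under ribosomal protein centring, among them Idh2 at −3.04, Mdh1 at −0.97 and Sdhb at −1.53. Of 22 glycolysis genes, 2 rose and 20 did not pass, 2 also when adjusted over the list alone: the glucose transporter gene Slc2a1 at 2.25 (SE 0.48, limma adjusted p = 0.00922) and Pfkfb3 at 1.97. Without non-primed replicate 3, 3 glycolysis genes were higher and 5 lower. Hk2 differed by 0.50 (SE 0.43, limma adjusted p = 0.376), or by 0.046 without non-primed replicate 3, Pfkfb4 by 1.07 and Gapdh by −0.72, none past the threshold. The kinase gene Mtor differed by −0.13 (SE 0.16, limma adjusted p = 0.532), and its sign turned without non-primed replicate 3, at 0.016. Of 36 mTOR complex components and regulators, 11 fell and 5 rose, or 11 and 4 when adjusted over the list alone, among them Deptor at −3.47, Rictor at −1.22, Depdc5 at −1.18 and Rps6kb1 at −1.06. The list did not pass as reported, and it passed without a filter, at camera adjusted p = 0.0228, and under fry, at 0.00782. The hypoxia factor gene Hif1a rose by 1.12 (SE 0.13, limma adjusted p = 0.00103), or by 0.727 under quantile normalization. Of 30 hypoxia and HIF1A target genes, 11 rose and 2 fell, or 9 and 2 when adjusted over the list alone, with a median of 0.68, among them Egln3 at 3.82, Stc2 at 6.86 and Narf at −1.20, and 10 rose and 4 fell without non-primed replicate 3. The camera adjusted p of the hypoxia list was 0.0337, and it was 0.204 without non-primed replicate 3 and 0.15 without primed replicate 3, where the median was 0.44. Camera adjusted p was 0.000157 for oxidative phosphorylation, 0.00542 for the TCA cycle, 0.878 for glycolysis and 0.215 for mTOR. With an estimated correlation the adjusted p was 0.453 for oxidative phosphorylation and the TCA cycle and 0.72 for hypoxia. The pigment-cell median was −7.36 in the same contrast.

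Of 28 p53 targets and senescence genes, 18 rose and 3 fell, or 19 and 3 when adjusted over the list alone, with a median of 1.90. Plk2 rose by 2.78 and the lysosomal galactosidase gene Glb1 by 1.05, and the lamin gene Lmnb1 at −2.74, Cdkn2d at −1.94 and Sesn1 at −1.68 were lower. The cell cycle inhibitor gene Cdkn2a rose by 5.20 (SE 1.64, limma adjusted p = 0.0389). Its 3 non-primed values were 8.94, 8.99 and 2.83, the difference was 3.16 without non-primed replicate 3, and the call was lost without primed replicate 1, 2 or 3, at limma adjusted p = 0.0883, 0.0895 and 0.111. Cdkn1a differed by 1.63 (SE 0.61, limma adjusted p = 0.0662) and was called without non-primed replicate 3, at 0.91 and limma adjusted p = 0.0193. Of 25 NRF2 and oxidative stress genes, 20 rose, 20 also when adjusted over the list alone, with a median of 1.51, among them Srxn1 at 3.08, Cat at 1.51, Nfe2l2 at 1.43 and Nqo1 at 4.59. Of 30 lysosome and autophagy genes, 19 rose and 1 fell, the regulator gene Tfeb at −1.76, or 20 and 2 when adjusted over the list alone, with a median of 0.90, among them Npc2 at 2.08, Lamp1 at 1.46 and Gla at 2.94. Of 26 immediate early and dissociation genes, 13 rose and 1 fell, Nr4a3 at −3.53, with the same counts when adjusted over the list alone. Their median was 1.41, and it was 2.28 without non-primed replicate 1. Fosl2 rose by 3.04, Btg2 by 2.33, Socs3 by 3.44 and Nr4a2 by 2.21. These 4 lists had a camera adjusted p of 0.00283 or less. With an estimated correlation the adjusted p was 0.529 for senescence and for immediate early genes and 0.453 for NRF2 and for lysosome. The pigment-cell median was −7.36 in the same contrast.

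Markers of other cell types also separated the groups. Of 19 macrophage and monocyte markers, 19 rose, 19 also when adjusted over the list alone, among them Cd14 at 7.87, Csf1r at 5.44, Itgam at 5.38 and Fcgr3 at 4.46. The remaining marker of that list, Aif1, lay below the expression filter. Of 8 adipocyte markers 6 rose, 8 when adjusted over the list alone, among them Car3 at 4.16, Lpl at 6.46, Pparg at 4.79 and Fabp4 at 6.86, while 7 others, Adipoq and Plin1 among them, lay below the expression filter, and the median of 5.02 was 1.03 without a filter. Of 7 tenocyte markers 6 rose, 6 also when adjusted over the list alone, among them Scx at 5.71, Col11a1 at 7.01 and Mkx at 6.23. Of 6 osteoclast markers 5 rose, 5 also when adjusted over the list alone, among them Nfatc1 at 2.75, Acp5 at 5.48, Oscar at 1.93 and Ctsk at 6.27. Of 10 pericyte and smooth muscle markers 7 rose, or 7 with 1 lower when adjusted over the list alone, among them Cox4i2 at 7.11, Steap4 at 7.25, Pdgfrb at 3.61 and Rgs5 at 4.94. Of 10 skeletal muscle markers 6 rose, 6 also when adjusted over the list alone, among them Chrna1 at 4.77, Acta1 at 5.49, Tnnt3 at 3.81 and Actn3 at 2.54. As written, the lists held 10 tenocyte, 10 osteoclast, 13 pericyte and 21 skeletal muscle markers. The rest lay below the expression filter, Tnmd, Dcstamp, Kcnj8, Myod1, Pax7 and Ckm among them. The camera adjusted p was 1.9e-05 for macrophages, 0.0032 for adipocytes, 0.00463 for tenocytes, 0.015 for osteoclasts, 0.0211 for pericytes and 0.0339 for skeletal muscle. With an estimated correlation it was 0.486 for macrophages, 0.549 for skeletal muscle and 0.453 for the others. The skeletal muscle call was lost without non-primed replicate 3, at camera adjusted p = 0.0631, without primed replicate 1, at 0.0732, and with library weights, at 0.0583. The pericyte call was lost at a mean of at least 7, at camera adjusted p = 0.109, and its median of 4.18 was 2.16 without a filter. The pigment-cell median was −7.36 in the same libraries.

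In total, camera called 31 of the 45 lists with at least 5 tested members, 27 up and 4 down, and 0 with an estimated correlation, where the lowest adjusted p was 0.453 and 2 lists had an unadjusted p under 0.05. Fry, which tests a list without comparing it with other genes, called 33. The lists that camera did not call had few genes past the threshold or genes that went both ways, as some called lists also did. Among the lists not called, 6 of 8 osteoblast and 4 of 7 keratinocyte markers rose and 1 of each fell. Of 52 ribosomal protein genes, 5 rose, 1 when adjusted over the list alone, among them Rps21 at 0.91 and Rps20 at 0.74, and the list median of 0.23 turned to −0.17 under quantile normalization and to −0.03 under ribosomal protein centring. This list passed without non-primed replicate 1 at camera adjusted p = 0.0228, without non-primed replicate 2 at 0.0433 and without primed replicate 1 at 0.0107, and without non-primed replicate 3 its median was 0.08, at 0.817. Of 23 purine and urate genes, 8 rose and 5 fell, with the same counts when adjusted over the list alone, among them Pnp at 2.89, Impdh1 at 1.12, the ectonucleotidase gene Nt5e at 7.66 and Gmps at −1.04. Of 18 heat shock and chaperone genes 7 rose and 3 fell, with the same counts when adjusted over the list alone, among them Hspb1 at 5.12 and Bag3 at 1.42, and the list passed without non-primed replicate 3, at camera adjusted p = 0.0474. Higher and lower genes numbered 6 and 6 of 29 in the ATF4 list, where Slc7a5 was at −3.31 and Cebpb at 4.29, 4 and 7 of 23 in the fatty acid list, where Hadha was at −0.78 and Ehhadh at −1.97, 6 and 3 of 23 in the cholesterol list, where Dhcr7 was at −2.08, and 3 and 3 of 22 in the unfolded protein list, where Pdia3 was at 1.41 and Edem1 at −0.62. When adjusted over the list alone these were 5 and 6, 4 and 7, 4 and 2, and 1 and 1. Without non-primed replicate 3, 5 genes of the ATF4 list were higher and 12 lower.

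Among the remaining cell type lists, higher and lower genes numbered 4 and 1 of 7 for keratinocytes, where Krt10 was at 5.24 and Krt19 at 8.26, 6 and 1 of 8 for osteoblasts, where Dlx3 was at 5.18 and Dlx6 at −7.92, 4 and 2 of 9 for endothelium, where Kdr was at 3.75 and Prox1 at −3.21, 3 and 4 of 14 for chondrocytes, where Cilp was at 6.44 and Sox6 at −2.96, and 2 and 3 of 12 for Schwann cells, where Pmp22 was at 2.88 and Sox10 at −3.22. When adjusted over the list alone these were 5 and 1, 6 and 1, 4 and 2, 3 and 4, and 1 and 2. As written, these lists held 18, 17, 19, 20 and 14 markers, and the rest lay below the expression filter. Without non-primed replicate 3, 4 endothelial genes were higher and 4 lower. The keratinocyte list passed without non-primed replicate 2, at camera adjusted p = 0.0433, and the osteoblast list passed under median centring, ribosomal protein centring and without a filter, at camera adjusted p = 0.0443, 0.0267 and 0.0112, and under fry, at 0.0308. The median, the mean and the test did not share a sign for fatty acid genes, with a median of −0.12, a mean of 0.51 and a downward test, for cholesterol genes, with a median of −0.03 and a mean of 0.22, for chondrocytes, with a median of 0.37, and for ATF4 genes, with a median of 0.05, where the tests also pointed down. Lists with under 5 tested members were not tested as lists. All 4 neutrophil genes tested rose, among them Camp at 7.08 and S100a8 at 6.29, while the other 10 of the list, S100a9 and Ly6g among them, lay below the expression filter. By contrast, Lck and Il2rb of the T, B and NK cell list and 3 erythroid genes did not pass. Of the 2 mast cell genes tested, out of 10 listed, Kit was lower at −2.80 and Gata2 higher at 1.56.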

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

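Centring on ribosomal protein genes, the counts per list without non-primed replicate 3 and the test of MITF targets found in no other list were chosen after seeing the data, and the other alternatives before. Over the planned and added settings that kept all 6 libraries, the count of genes higher in primed lay between 2789 and 5750. That of genes lower lay between 2679 and 4965. Leaving out 1 library gave 3214 to 4677 higher and 2375 to 3923 lower. Of the genes shared with the 7476 calls, 0 changed sign under any of these settings. Only genes called again count here, and they numbered as few as 5536, without primed replicate 3. The median difference over tested genes was 0.04 as reported, −0.064 after median centring, −0.232 after quantile normalization and −0.224 after ribosomal protein centring, so small shifts of lists are relative to the scaling. The 31 lists called fell to 0 with an estimated correlation. Among other settings the count of lists lay between 28 and 35, and leaving out 1 library gave 30 to 33. With the replicate number as a block, 3618 genes were higher and 2679 lower, 31 lists were called, and C3ar1 at limma adjusted p = 0.0548, Cdkn2a at 0.0592 and the hypoxia list at camera adjusted p = 0.0503 did not pass, while the keratinocyte list did, at 0.0487. Same-numbered libraries deviated together with r = 0.0654, −0.132 and −0.118. With 3 libraries per group, such values cannot tell whether the numbers pair the samples. Cdkn2a was not called either without a filter or with a constant prior variance, at limma adjusted p = 0.0694 and 0.052. Over all its settings its adjusted p lay between 0.000149 and 0.111. The hypoxia list did not pass with library weights or under fry, at adjusted p = 0.279 and 0.158. The heat shock list passed with weights and under fry, at 0.0471 and 0.00123, the ribosomal protein list at a mean of at least 7, at 0.0302, and the keratinocyte list without a filter, under median and ribosomal centring and under fry, at 0.0128, 0.0443, 0.0231 and 0.00744. Among called results, moves of over 1.5-fold with the same sign that the report does not give were those of lysosome at 0.545 and skeletal muscle at 1.39 under quantile normalization, Cdkn2a at 3.40, immediate early genes at 0.858, interferon-stimulated genes at 1.40 and hypoxia at 0.453 with weights, and hypoxia at 0.415 under ribosomal centring. Over all settings the values of results not called lay between −0.4 and 0.0156 for Mtor, 0.0442 and 0.733 for Hk2, 0.914 and 2.03 for Cdkn1a, −0.258 and 0.283 for ATF4, −0.293 and 0.191 for cholesterol, −0.267 and 0.734 for chondrocytes, −0.166 and 0.325 for ribosomal proteins, −0.572 and 0.761 for endothelium, −0.383 and 0.164 for fatty acids, −0.395 and 0.296 for glycolysis, 0.176 and 0.588 for heat shock, 1.34 and 3.45 for keratinocytes, −0.377 and 0.0109 for mTOR, 1.94 and 2.95 for osteoblasts, −0.126 and 0.31 for purine, −0.658 and 1.07 for Schwann cells and −0.286 and 0.204 for unfolded protein genes.

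Directions that turned, with causes not tested, were those of results that had not passed. Mtor turned to 0.0104 with library weights. The fatty acid median was 0.0508 without a filter and 0.122 with weights. The ATF4 median was −0.0561, −0.258, −0.202 and −0.216 under median centring, quantile normalization, weights and ribosomal centring, and the glycolysis median −0.0648, −0.395, −0.304 and −0.224. The unfolded protein median was −0.0246, −0.286 and −0.184 under median, quantile and ribosomal scaling. Under quantile normalization and ribosomal centring, the ribosomal protein median was −0.166 and −0.0346, endothelium −0.572 and −0.0555 and purine −0.0133 and −0.126. Under quantile normalization and weights, chondrocytes were at −0.267 and −0.0207 and Schwann cells at −0.237 and −0.658. With weights the cholesterol median was 0.191. Leaving out 1 library, the ranges were −0.218 to 0.173 for cholesterol synthesis, −0.227 to 0.0156 for Mtor, −0.12 to 0.283 for ATF4 and amino acid response, −0.171 to 0.734 for chondrocytes and cartilage, −0.163 to 0.164 for fatty acid synthesis and oxidation, −0.322 to 0.296 for glycolysis, −0.148 to 0.0109 for mTOR complex components and regulators, −0.245 to 1.07 for Schwann cells and nerve and −0.00169 to 0.204 for unfolded protein response. The missing counts limit the statement of precision for genes of low value.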

Other observations

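The camera test of all MITF targets and the tests of other splits of the libraries were fixed before their results were seen. The tests of MITF targets found in no other list, Xist, keratins, ribosomal protein genes, deficits and chromosome 6 were fixed only after. The comparison of MITF targets with random lists was not part of the test fixed before. The genes in the rest of this paragraph were chosen after their values were seen. The X-linked genes Brs3, Luzp4 and Xlr3c and the RNA-binding gene Lin28b were higher in the libraries labelled non-primed. Brs3 had a mean of 11.02 ± 0.326 (SD, n = 3) in them and 2.03 ± 0.274 in those labelled primed, Luzp4 had 8.29 ± 0.151 and 1.31 ± 0.488, Xlr3c 9.87 ± 0.123 and 1.54 ± 0.0566, and Lin28b 7.53 ± 0.828 and 1.47 ± 0.516, with limma adjusted p of 0.000496 or less. Among purine genes, Ampd3 at 4.33, Gda at 6.01 and the xanthine dehydrogenase gene Xdh, whose enzyme makes urate, at 6.59 (limma adjusted p = 0.0059) were higher in the libraries labelled primed and Ppat at −1.48, Pfas at −1.23 and Gart at −0.91 were lower, and the purine list as a whole did not pass (camera adjusted p = 0.773). The cell cycle inhibitor gene Cdkn2b had values of 7.72, 7.93 and 2.82 in non-primed replicates 1, 2 and 3 and of 12.18, 12.20 and 12.50 in the libraries labelled primed. Its neighbour Mtap had a mean of 14.26 and 13.13 in the 2 groups.

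Pigment-cell genes were abundant in the 3 libraries labelled non-primed. The tables argue against fibroblasts of the same kind and karyotype with pigment genes switched on, though not against fibroblasts that had lost an X chromosome or Xist, since the X-inactivation transcript Xist, at 9.23, 9.43 and 4.16 there against 13.98, 14.68 and 14.60, differed by 6.813 (SE 1.39, limma adjusted p = 0.00788) while 4 Y-linked genes stayed at or below 2.06 in every library. They also argue against skin carried over with its keratinocytes, since Krt5, Krt14, Krt1 and Krt10 reached at most 3.012 there. Keratins cannot speak to skin cells in cultures without keratinocytes, so a skin origin of the pigment cells stays open. A pigment-cell population that supplies much of the RNA in these libraries is a candidate explanation: among 33 MITF target genes, 3 of them in lists already tested, the median difference was −0.6208, with 16 lower and 9 higher (camera p = 0.0426, and p = 0.371 with an estimated correlation; without the 3, p = 0.03 and 0.282), at the 0.05 percentile of 10000 random lists matched on expression, though 31 of the 33 also had a mean of at least 7 in the libraries labelled primed. Whether such cells came from the animals, from another culture or from mislabelled libraries stays open, as does the number of injections, which was not separated from the cell type.

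Fibroblast genes were higher in non-primed replicates 1 and 2 than in replicate 3, in both for 52 of 58 matrix genes, by a median of 2.64. The tables argue against scaling of replicate 3 as a whole, since ribosomal protein genes differed by a median of only 0.423 (95% interval over genes 0.346 to 0.511). Depth stays open, since it is unknown and these genes cannot show how it acts on lower values. In replicate 3 the median was 14.38 for ribosomal protein genes and 5.98 for collagen genes. Reads carried over from the primed libraries stay open: in genes at least 8 below the primed mean in replicate 3, the deficit of 25 chemokine and cytokine genes exceeded that of 24 matrix genes by 0.64 (95% interval −0.0742 to 1.03) in replicate 1 and by 0.4019 (−0.0074 to 1.38) in replicate 2, where carry-over needs 0 and the bound was 1. This cutoff gave the smallest differences of 9 cutoffs from 2 to 10, tried after the result was seen, which reached 0.82, with both intervals above 0 at 2 of them, and without a cutoff replicate 1 gave 1.20, so these values do not decide. A minority of fibroblasts in replicates 1 and 2 was not tested and stays open too.

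Genes of chromosome 6 were lower in the libraries labelled primed than those of other chromosomes, with a median shift of −0.53 over 546 protein-coding genes with a mean of at least 7, and −0.52, −0.54 and −0.43 against non-primed replicates 1, 2 and 3. The largest shifts elsewhere were −0.29 on chromosome 12 and 0.32 on chromosome 14. The tables argue against a few genes or 1 cluster, since all 14 windows of 10 Mb with at least 10 genes lay below the median of the genome, and against chance placement of genes, with a permutation p of 1e-04, the smallest that 10000 draws can give. These draws place each gene by itself, and 3 other chromosomes, 12, 14 and 19, also lay beyond every draw, so this p does not single out chromosome 6. An extra copy of chromosome 6 in the cells of the libraries labelled non-primed is one hypothesis, not tested here, since no DNA data were used, and a difference in cell type stays open.

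With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Each split other than the real one mixes the 2 groups on both sides, so their difference enters the spread and lowers the gene counts. Low gene counts there are thus no measure of chance. By limma the real split gave 4113 higher and 3363 lower genes, 1 of 10 splits with as many in each case, and the highest other split gave 0, with 20 to 332 genes at an unadjusted p under 0.05 against 8484 in the real split. Camera called 31 lists in the real split, 4 of 10 splits called as many, and the highest other split called 37.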
